A study of Arabidopsis thaliana with 72 samples.

How the data were processed

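Roots and shoots of Arabidopsis thaliana, accession Wassilewskija, were measured on 72 ATH1 arrays: 24 groups of 3, one for each tissue, pressure (10 or 97 kPa) and time (1, 3, 6, 12, 48 or 72 h). Per the labels, plants 10 days old were moved to pressure chambers with 2.1 kPa oxygen at 10 kPa and 21 kPa oxygen at 97 kPa, with 0.05 kPa carbon dioxide in both, under constant light. Each replicate came from a separate chamber and was 1 tube of about 12 plants kept in RNAlater, which was then divided into roots and shoots; 29 tubes gave both a root and a shoot array. RNA was labelled with a 3′ IVT kit.

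The deposited values are signal intensity on a linear scale, made by the authors with MAS5 and Affymetrix Expression Console per the submitters' processing notes; versions and settings are not given in the sources used here. On each array the mean after trimming 2% of probe sets at each end was 500, which is the scaling applied before deposition, and no further normalization was used. The table holds 22810 probe sets, of which 64 are control probe sets that were used only for quality ratios. The given tables name 1 gene for 13513 probe sets, and 13436 of these matched the reference table; 503 name several genes and 8794 are not listed, and these last count in totals but are never named. Arrays give no read depth, so their number, 3 per group, limits the precision.

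Values were analysed as log2 of signal plus 8.90, the 10th percentile of all values. Probe sets were tested where they reached the 40th percentile of their array in at least 3 arrays, which left 16667 in roots, 15794 in shoots and 17901 in the fit of both tissues. In that last fit a probe set could pass through the arrays of 1 tissue alone. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance), 1 fit for the 36 arrays of each tissue and 1 for all 72, with 24 and 48 residual degrees of freedom. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p below 0.05. Contrasts were 10 kPa minus 97 kPa at each time, the late (48 and 72 h) minus early (1 and 3 h) pressure effect, the same late minus early difference at 97 kPa, and the root minus shoot pressure effect over the 6 times.

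Before the data were examined, the contrasts, the test, the pseudocount and filter, the alternative settings, 33 gene lists with 713 genes (6 of them cell type markers) and the rule for naming genes were fixed. By that rule each pressure comparison names the 5 largest increases and 5 largest decreases among called probe sets of 1 gene whose 3 values at 10 kPa all lay beyond all 3 at 97 kPa, the late minus early and root minus shoot contrasts name their 5 largest changes each way, and each list described names up to 4 members with the largest change. Of these genes the text gives mainly those that kept their call under the alternatives, and says where one did not. ADH1 and PDC1 were also to be named, but the given tables name no probe set for either. Of the list genes 700 had an accepted name in the tables, 13 were left out because the name differed, and 119 had a named probe set. Each list is thus tested in part, and counts below are out of its tested members. These were 18 of 42 low-oxygen genes, 4 of 22 glycolysis, 4 of 22 sugar starvation and 3 of 25 cell division genes. In shoots they were 4 of 24 flavonoid and 4 of 42 dehydration genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all lists and contrasts of a fit. Lists with fewer than 3 tested members were not tested as sets, a minimum added after the annotation was seen, which left 14 lists in roots and 17 in shoots. In each set called, the median, the mean and the test had the same sign.

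The alternatives fixed then were quantile normalization, no pseudocount (values floored at 1.87), a pseudocount of 50.8, no filter, a filter at the 60th percentile, no variance trend, a 2-fold minimum, a replicate block, each replicate left out, only the 6 arrays of a comparison, leaving out the 4 arrays of 72 h numbered apart, and the tube as a random block. Leaving out the 48 and 72 h arrays and adding the mean log2 3′ to 5′ ratio of the plant control genes of each array as a covariate were chosen after the data were seen. The procedure was tested on simulated data, 20 draws of random noise with each probe set's own mean and spread and known changes added to 200 probe sets: at 6 h in roots it recovered 45.8% of changes of log2 1 and 80.2% of log2 2, with 5.53% of calls false, and in shoots 59.3% and 91.7%, with 5.32% false. For the root minus shoot contrast, 1 draw with changes of log2 1 gave 67% recovered and 3.60% false. The simulated noise had the same spread at every time and was independent between probe sets. Replicates were less alike at 48 and 72 h, so these shares do not carry over to comparisons that use those times.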

Results

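The labels pose the question of how transcripts in roots and shoots respond over 72 h when 10-day-old Arabidopsis plants of the Wassilewskija accession are moved to low atmospheric pressure. Each pressure comparison set 3 arrays at 10 kPa, with 2.1 kPa oxygen, against 3 arrays at 97 kPa, with 21 kPa oxygen, so total pressure and oxygen changed together. The sample descriptions give the control pressure as 101 kPa where other labels give 97 kPa. Changes are log2 ratios of the signal at 10 kPa over that at 97 kPa, with the standard error (SE) of the model, and a gene is said to have risen or fallen where its adjusted p was below 0.05. Array numbers in the descriptions came in runs that followed pressure, so number run and pressure could not be told apart. The controls of 1 and 3 h were numbered in another run than most of those of 6 to 72 h, so late minus early contrasts also compare runs. The exception was a run with 1 array of each pressure and tissue at 72 h: there the median difference of the 18 core low-oxygen genes was 0.83 in the root pair and -0.20 in the shoot pair, against 1.41 and -0.69 over all arrays of that time, with no test possible in 1 pair. The 97 kPa array of the root pair had a GAPDH 3′ to 5′ signal ratio of 1312, against 342.9 in its partner. Its actin 3′ to middle ratio was lower than that of its partner, 11.6 against 20.6.

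At 1 h, roots at 10 kPa had raised the core genes of the low-oxygen response as a block, and had lowered a wall-loosening gene. AT5G10040 reached a signal of 26290 ± 2106 at 10 kPa against 82.8 ± 21.9 at 97 kPa (SD, n = 3), a log2 change of 8.19 (SE 0.39, adjusted p = 9.73e-18). AT4G33560 rose by 5.86 (SE 0.36), AT3G29970 by 5.45 (SE 0.40) and AT4G10270 by 5.40 (SE 0.47) on the log2 scale. PDC2, which encodes the fermentation enzyme pyruvate decarboxylase, rose by 3.53 (SE 0.21, adjusted p = 4.26e-15), and CML38, a calmodulin-like gene, by 4.68 (SE 0.54, adjusted p = 9.17e-08); these genes and EXPA15, below and in later comparisons, were picked out after their values were seen. Every one of the 18 tested core low-oxygen genes rose, 18 also when adjusted over the list alone, with a median log2 change of 4.03 and a range of 2.10 to 8.19; the set test gave an adjusted p of 6.29e-93, and adjusted p = 1.26e-05 with an estimated correlation. GH3.3, which conjugates auxin to amino acids, rose by 3.29 (SE 0.66), and PYE, a transcription factor of the iron deficiency response, by 1.60 (SE 0.26). The control signal of GH3.3 was 14.5 ± 7.18 (SD, n = 3), near the lower end of the range, so the size of its change depends on the pseudocount. Among the decreases, the expansin gene EXPA15 fell by 1.00 (SE 0.21), AT4G25250 by 1.74 (SE 0.36) and AT2G34610 by 1.64 (SE 0.33). The cytosolic ribosomal protein genes had a median of -0.38: 1 of 7 fell, 6 fell when adjusted over the list alone, and the set was lower at an adjusted p of 0.000708, with adjusted p = 0.298 with an estimated correlation. That call ended with quantile normalization (adjusted p = 0.0924, the highest of 16 alternatives, which began at 0.000143). The auxin genes were called higher (median 0.41, 1 of 6 rose, 1 when adjusted over the list alone, adjusted p = 0.0479; adjusted p = 0.151 with an estimated correlation). Their call ended without 10 kPa replicate 1 (0.12), 10 kPa replicate 2 (0.0729), 97 kPa replicate 1 (0.0791) or 97 kPa replicate 3 (0.063), with quantile normalization (0.0537), no pseudocount (0.0546), only the 6 arrays (0.0728) or the ratio covariate (0.0644, median 0.37), and without the 48 and 72 h arrays (0.0681). In all, 594 of 16667 probe sets were called, 355 higher and 239 lower at 10 kPa. The number was 387 without 10 kPa replicate 1, 331 without 10 kPa replicate 2, 351 without 97 kPa replicate 2 and 335 without 97 kPa replicate 3. It was over 1.5 times higher with only the 6 arrays or without the 48 and 72 h arrays.

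At 3 h the low-oxygen genes stayed high in roots, the glycolytic gene GAPC2 rose, and EXPA7, EXPA15, BCAT4 and ATERDJ3B fell. AT5G10040 had a log2 change of 6.86 (SE 0.39), AT3G29970 of 6.45 (SE 0.40), and AT4G30380 went from 4.41 ± 2.37 at 97 kPa to 721.4 ± 86.4 at 10 kPa (SD, n = 3; log2 change 5.79, SE 0.75, adjusted p = 1.06e-06). The control signal lay at the lower end of the range, so the size of that change depended on the pseudocount: 7.49 with none and 3.80 with the higher one. GAPC2, the cytosolic glyceraldehyde-3-phosphate dehydrogenase, rose by 1.49 (SE 0.25). EXPA7, an expansin of root hairs, fell by 2.03 (SE 0.38, adjusted p = 0.00037) and EXPA15 by 1.36 (SE 0.21). BCAT4, of methionine-derived glucosinolate synthesis, fell by 1.32 (SE 0.27), and ATERDJ3B, a co-chaperone of the endoplasmic reticulum, by 0.93 (SE 0.15). AT4G16000 fell by 2.50 (SE 0.59) from 100.1 ± 26.3 to 10.4 ± 4.96, near the lower end of the signal range. All 18 low-oxygen genes rose again (18 when adjusted over the list alone), with a median of 3.33 and adjusted p = 0.000144 with an estimated correlation. Nuclear photosynthesis genes were lower as a set: none of 9 was called over all genes, 2 fell when adjusted over the list alone, the median was -0.62, and adjusted p = 0.0203, with adjusted p = 0.512 with an estimated correlation. This call ended without 10 kPa replicate 2 (0.0705) or 10 kPa replicate 3 (0.106), within a range of 0.00071 to 0.106 over 16 alternatives. In total, 1000 probe sets were called, 428 higher and 572 lower, on arrays whose GAPDH 3′ to 5′ signal ratio was 76.0 ± 13.2 at 10 kPa and 164.0 ± 22.9 at 97 kPa (SD, n = 3).

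**Figure D1:**
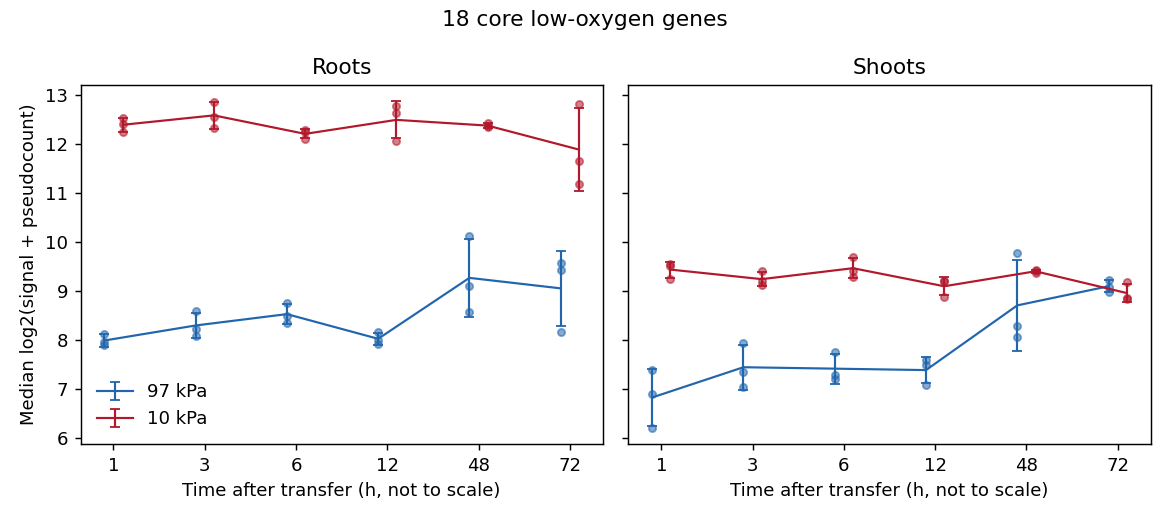
Median log2 signal of the 18 core low-oxygen genes on each array against time in hours, roots and shoots in separate panels, 97 kPa in blue and 10 kPa in red; points are arrays and lines join group means with SD (n = 3). In roots at 1 h the 10 kPa group had a mean of 12.40 against 7.99 at 97 kPa, and in shoots the 97 kPa group went from 6.82 at 1 h to 9.10 at 72 h.

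After 6 h, roots at 10 kPa held the low-oxygen genes high, and BZIP60 rose while ATERDJ3B and CRT1b fell. BZIP60, a transcription factor of the unfolded protein response, rose by 0.93 (SE 0.17, adjusted p = 0.000291). ATERDJ3B fell by 1.06 (SE 0.15) and CRT1b, a calreticulin, by 0.90 (SE 0.15, adjusted p = 7.51e-05). BCAT4 fell by 1.56 (SE 0.27) and EXPA15 by 0.97 (SE 0.21), while GAPC2 rose by 1.35 (SE 0.25). The largest decreases among genes named by the rule were AT5G62330, which fell by 3.53 (SE 0.64) from 211.9 ± 91.7 to 9.31 ± 2.46, near the lower end of the range, and AT4G10280, which fell by 3.06 (SE 0.41); AT2G41730 rose by 4.42 (SE 0.38). BBM, a transcription factor of embryo and root meristem development, fell by 2.34 (SE 0.64, adjusted p = 0.0149), but lost its call without 10 kPa replicate 2 (0.0874), 10 kPa replicate 3 (0.0624), 97 kPa replicate 1 (0.0674) or 97 kPa replicate 3 (0.0544). Of the core low-oxygen genes, 17 rose and none fell, 18 rose when adjusted over the list alone, and the median was 3.48 (adjusted p = 0.000498 with an estimated correlation). Glycolysis genes were higher (2 of 4 rose, 3 when adjusted over the list alone, median 0.49, adjusted p = 0.0176; adjusted p = 0.0667 with an estimated correlation), a call that ended without 97 kPa replicate 2 (0.0544; range over the alternatives 0.00278 to 0.0544). Ribosomal protein genes were lower (2 of 7 fell, 3 when adjusted over the list alone, median -0.18, adjusted p = 0.0396; adjusted p = 0.487 with an estimated correlation), and AT5G02870 among them fell by 0.49 (SE 0.12). The ribosomal call ended without 10 kPa replicate 2 (0.0523), 10 kPa replicate 3 (0.208) or 97 kPa replicate 1 (0.105), with the stricter filter (0.051), with only the 6 arrays (0.0568) and with the ratio covariate (0.0644, median -0.16). Altogether 1531 probe sets were called, 765 higher and 766 lower.

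At 12 h, SWEET11 and SWEET3 were lower in roots, and low-oxygen and glycolysis genes were higher. AT3G29970 had the largest increase, from 99.3 ± 46.3 at 97 kPa to 33490 ± 4764 at 10 kPa (SD, n = 3), a log2 change of 8.35 (SE 0.40, adjusted p = 7.59e-18). SWEET11, a sucrose exporter of the phloem, fell by 2.08 (SE 0.29, adjusted p = 2.67e-06), and SWEET3, of the same family, by 2.77 (SE 0.43). AT4G10280 fell by 3.92 (SE 0.41) and AT4G14695 by 3.34 (SE 0.29). GSTU25, a glutathione S-transferase, rose by 1.89 (SE 0.33). CRT1b fell by 1.19 (SE 0.15), ATERDJ3B by 0.99 (SE 0.15), EXPA15 by 1.04 (SE 0.21) and XTH16, a xyloglucan endotransglucosylase, by 1.55 (SE 0.30), whereas BZIP60 rose by 0.86 (SE 0.17). GAPC2 rose by 1.54 (SE 0.25) and TPI, triose phosphate isomerase, by 0.65 (SE 0.15). With them the glycolysis genes were higher as a set (2 of 4 rose, 3 when adjusted over the list alone, median 0.57, adjusted p = 0.0084), also at adjusted p = 0.043 with an estimated correlation. The low-oxygen genes had 17 of 18 increases, 17 when adjusted over the list alone, with a median of 3.76 (adjusted p = 0.000498 with an estimated correlation). Photosynthesis genes were now higher (2 of 9 rose, 2 when adjusted over the list alone, median 0.62, adjusted p = 0.0203; adjusted p = 0.512 with an estimated correlation). That call ended without 10 kPa replicate 1 (0.0575), 10 kPa replicate 3 (0.162) or 97 kPa replicate 2 (0.0526), within 0.000715 to 0.162 over the alternatives. Of the tested probe sets 2001 were called, 943 higher and 1058 lower, and 1262 were called without 10 kPa replicate 3.

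At 48 h the roots combined a smaller pressure effect in low-oxygen genes with higher PSAE-1 and PSBY and a lower SWEET11. ICL, isocitrate lyase of the glyoxylate cycle, rose from 36.5 ± 43.6 to 864.6 ± 382.7 (SD, n = 3; log2 change 4.57, SE 0.88, adjusted p = 0.000444). PSAE-1, of photosystem I, rose by 1.87 (SE 0.35) and PSBY, of photosystem II, by 1.65 (SE 0.32); 3 of 9 photosynthesis genes rose, 6 when adjusted over the list alone, with a median of 1.02 (adjusted p = 0.000552; adjusted p = 0.371 with an estimated correlation). That median ranged from 0.41, without 97 kPa replicate 1, to 1.495, without 97 kPa replicate 3. On the same arrays, 300 other probe sets were at least 10 times higher in 10 kPa shoots than in 97 kPa roots, and of these 78 were called higher and none lower. Their choice used the same 97 kPa root arrays and so favours a rise. Shoot tissue in these roots stays open. SWEET11 fell by 2.75 (SE 0.29, adjusted p = 1.21e-08), GAT1_2.1, a class I glutamine amidotransferase, by 3.17 (SE 0.68) and AT4G25250 by 3.31 (SE 0.36). EXPB1 fell by 1.44 (SE 0.30) and EXPB3 rose by 0.93 (SE 0.15); of the 13 expansin and xyloglucan endotransglucosylase genes 1 rose and 4 fell, 1 and 4 when adjusted over the list alone, and the set was not called (median -0.41, adjusted p = 0.41). EXPA15 fell by 0.67 (SE 0.21, adjusted p = 0.0291), a call that ended without 10 kPa replicate 2 (0.133) or 97 kPa replicate 1 (0.252) and with only the 6 arrays (0.181). Glycolysis genes were higher (3 of 4 rose, 3 when adjusted over the list alone, median 0.74, mean 0.40, adjusted p = 0.0133; adjusted p = 0.0553 with an estimated correlation), with GAPC2 up by 1.22 (SE 0.25). Core low-oxygen genes had a median of 2.44, with 16 of 18 increases and 17 when adjusted over the list alone (adjusted p = 0.0072 with an estimated correlation). Their median log2 signal per array at 10 kPa was 12.349 to 12.435, against 12.245 to 12.537 at 1 h. At 97 kPa it was 8.564 to 10.134, against 7.887 to 8.126 at 1 h. Cell division genes were lower (1 of 3 fell, 3 when adjusted over the list alone, median -0.63, adjusted p = 0.0479; adjusted p = 0.267 with an estimated correlation), but not without 10 kPa replicate 1 (0.0728), 10 kPa replicate 2 (0.076), 97 kPa replicate 1 (0.0508) or 97 kPa replicate 3 (0.179), nor with the higher pseudocount (0.0603), the stricter filter (0.051) or the ratio covariate (0.0644, median -0.61). Replicates were less alike than at early times, with correlations across genes down to 0.859 between arrays of the 97 kPa roots, and the GAPDH 3′ to 5′ ratio was 155.0 ± 54.4 at 10 kPa and 272.1 ± 81.7 at 97 kPa (SD, n = 3). A total of 1918 probe sets were called, 888 higher and 1030 lower, and the number was over 1.5 times lower with only the 6 arrays.

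At 72 h fewer low-oxygen genes were called in roots than at 48 h, the median of the list was lower, and SWEET11 was again low. AT5G10040 rose by 5.36 (SE 0.39), AT3G29970 by 5.17 (SE 0.40) and AT4G33560 by 4.06 (SE 0.36). PDC2 rose by 0.81 (SE 0.21, adjusted p = 0.0128) but lost its call without 10 kPa replicate 1 (0.0938), 97 kPa replicate 2 (0.0561) or the 4 arrays numbered apart (0.0554), and with only the 6 arrays (0.147). For the list, 10 of 18 rose, 16 rose when adjusted over the list alone, and the median was 1.41 with a mean of 2.12 (adjusted p = 0.0219 with an estimated correlation). That median was 0.70 without 10 kPa replicate 1, the array highest in these genes, and 2.12 without the 4 arrays numbered apart. SWEET11 fell by 2.74 (SE 0.29, adjusted p = 1.55e-08), and AT3G16530 by 3.54 (SE 0.56). EXLA2, an expansin-like gene, fell by 2.34 (SE 0.44, adjusted p = 0.000485), which was not called with only the 6 arrays (0.131). EXPA15 fell by 0.70 (SE 0.21, adjusted p = 0.0293), so it was called lower in roots at every time, but here the call ended without 10 kPa replicate 2 (0.0719), 10 kPa replicate 3 (0.135) or 97 kPa replicate 1 (0.135), without the 4 arrays numbered apart (0.0693), and with only the 6 arrays (0.146) or the ratio covariate (0.0574 at -0.68, SE 0.22). Sugar starvation genes were lower (1 of 4 fell, 3 when adjusted over the list alone, median -0.60, adjusted p = 0.0164; adjusted p = 0.232 with an estimated correlation), except without 10 kPa replicate 1 (0.0894; range over the alternatives 0.0057 to 0.0894). The comparison called 1360 probe sets, 588 higher and 772 lower. With only the 6 arrays the count was over 1.5 times lower.

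**Figure D2:**
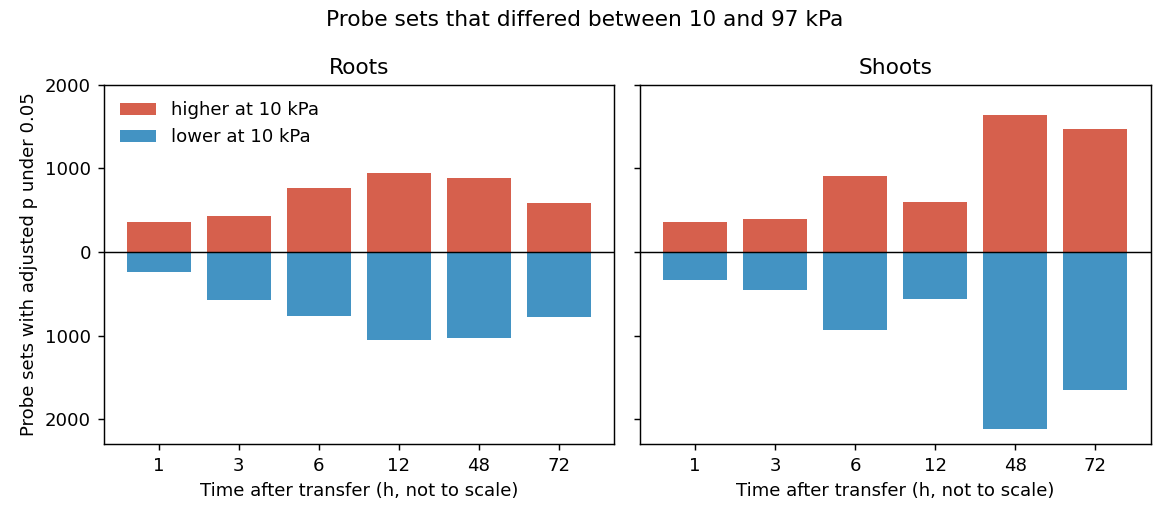
Number of probe sets called higher (upward bars) and lower (downward bars) at 10 kPa than at 97 kPa against time in hours, in roots and shoots. In shoots the total went from 1171 at 12 h to 3750 at 48 h, while roots stayed between 594 and 2001.

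In shoots at 1 h the low-oxygen genes rose too, by less than in roots, and LHCB4.2 and PSBW fell. AT4G33560 rose from 70.3 ± 18.22 to 1702 ± 471.1 (SD, n = 3), a log2 change of 4.42 (SE 0.38, adjusted p = 3.26e-09); PDC2 rose by 1.94 (SE 0.23) and CML38 by 2.15 (SE 0.44). Of the 18 low-oxygen genes 16 rose, 17 when adjusted over the list alone, with a median of 2.08 (adjusted p = 1.73e-32, and adjusted p = 0.00448 with an estimated correlation). LHCB4.2, an antenna protein of photosystem II, fell by 1.21 (SE 0.22, adjusted p = 0.000858) and PSBW by 0.60 (SE 0.14). Among the photosynthesis genes 6 of 9 fell and all 9 when adjusted over the list alone, with a median of -0.49 (adjusted p = 1.02e-09; adjusted p = 0.0668 with an estimated correlation). GI, a circadian clock gene, rose by 1.11 (SE 0.21), UGT78D2, a flavonoid glucosyltransferase, by 1.48 (SE 0.22) and PYE by 1.30 (SE 0.23). EXPA8, an expansin gene, fell by 1.76 (SE 0.32), and AT2G15830 by 2.53 (SE 0.32). Sugar starvation genes were lower (1 of 4 fell, 1 when adjusted over the list alone, median -0.47, adjusted p = 0.0226; adjusted p = 0.304 with an estimated correlation), but not without 10 kPa replicate 1 (0.0565) or 10 kPa replicate 2 (0.0715), over a range of 0.00574 to 0.0715. Of 15794 probe sets 689 were called, 358 higher and 331 lower. This count was 323 without 10 kPa replicate 2, 396 without 97 kPa replicate 2 and 264 without 97 kPa replicate 3.

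At 3 h the low-oxygen genes were higher in shoots and EXPA8 was lower. EXPA8 fell by 2.17 (SE 0.32, adjusted p = 6.27e-05), SUFE2, of plastid iron-sulfur cluster assembly, by 2.77 (SE 0.50), LHCB4.2 by 1.24 (SE 0.22) and AT1G73120 by 2.44 (SE 0.44). AT5G66985 rose by 4.29 (SE 0.50) and AT5G10040 by 5.03 (SE 0.64). PDC2 rose by 1.02 (SE 0.23), and 11 of 18 low-oxygen genes rose (14 when adjusted over the list alone), with a median of 1.21 and a mean of 1.90 (adjusted p = 0.039 with an estimated correlation). The other sets called did not keep their calls with an estimated correlation. Photosynthesis genes were lower (1 of 9 fell, 2 when adjusted over the list alone, median -0.26, adjusted p = 0.00826; adjusted p = 0.342 with an estimated correlation). Flavonoid genes were higher (2 of 4 rose, 3 when adjusted over the list alone, median 0.97, adjusted p = 0.00523; adjusted p = 0.152 with an estimated correlation). Chlorophyll synthesis genes were lower (2 of 3 fell, 2 when adjusted over the list alone, median -0.76, adjusted p = 0.0189; adjusted p = 0.218 with an estimated correlation), except without 10 kPa replicate 1 (0.0561; range 0.00524 to 0.0561). Sugar starvation genes were lower (1 of 4 fell, 1 when adjusted over the list alone, median -0.60, adjusted p = 0.016; adjusted p = 0.285 with an estimated correlation), except without 97 kPa replicate 3 (0.0758; range 0.00284 to 0.0758). Dehydration genes were higher (1 of 4 rose, 2 when adjusted over the list alone, median 1.06, adjusted p = 0.0308; adjusted p = 0.199 with an estimated correlation), but not without 10 kPa replicate 2 (0.112) or 97 kPa replicate 1 (0.114), nor with the stricter filter (0.118) or only the 6 arrays (0.109). The shoots had 853 called probe sets, 401 higher and 452 lower; the count was 333 without 10 kPa replicate 1, 529 without 97 kPa replicate 1 and 307 without 97 kPa replicate 3. It was over 1.5 times higher with only the 6 arrays.

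At 6 h, AKINBETA1 and MCCB fell in shoots, while COR15A, COR15B and the starch synthesis gene APL3 rose. AKINBETA1, a regulatory subunit of the SnRK1 kinase, fell by 2.03 (SE 0.31, adjusted p = 1.41e-05), and MCCB, of leucine breakdown, by 0.85 (SE 0.18). With them 3 of 4 sugar starvation genes fell, 3 when adjusted over the list alone, with a median of -1.03 (adjusted p = 0.000472; adjusted p = 0.129 with an estimated correlation). COR15A and COR15B, chloroplast proteins of cold and dehydration, rose by 2.35 (SE 0.41) and 2.16 (SE 0.28); the other 2 of 4 dehydration genes were not called, and the set was not either (adjusted p = 0.127). APL3, of ADP-glucose pyrophosphorylase, rose by 2.12 (SE 0.41, adjusted p = 0.000364). EXPA8 fell by 2.92 (SE 0.32), CHLM, of chlorophyll synthesis, by 0.98 (SE 0.18), WES1, of auxin conjugation, by 1.00 (SE 0.23) and SWEET11 by 0.96 (SE 0.24), while EXPB3 rose by 1.24 (SE 0.26). Among the genes named by the rule, AT3G03270 rose by 4.18 (SE 0.24) and AT1G73120 fell by 3.73 (SE 0.44). Low-oxygen genes had 10 of 18 increases, 12 when adjusted over the list alone, and a median of 0.98, with a range of -1.22 to 4.60 (adjusted p = 1.36e-10; adjusted p = 0.116 with an estimated correlation). Ribosomal protein genes were higher (1 of 7 rose, 1 when adjusted over the list alone, median 0.23, adjusted p = 0.0142; adjusted p = 0.342 with an estimated correlation), except with quantile normalization (0.095) and without 10 kPa replicate 2 (0.0538), over a range of 0.0042 to 0.095. The comparison called 1848 probe sets, 913 higher and 935 lower, and 1222 without 10 kPa replicate 1.

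At 12 h DFR was higher in shoots, and AKINBETA1 and EXPA8 were lower; none of the sets called kept its call with an estimated correlation. DFR, dihydroflavonol reductase of anthocyanin synthesis, rose by 2.16 (SE 0.35, adjusted p = 8.54e-05). Flavonoid genes were higher (3 of 4 rose, 3 when adjusted over the list alone, median 1.34, adjusted p = 0.000472; adjusted p = 0.0703 with an estimated correlation). TBL26, of a family that includes wall acetyltransferases, rose by 3.72 (SE 0.50) and COR15A by 2.28 (SE 0.41). AKINBETA1 fell by 1.39 (SE 0.31) and MCCA, of leucine breakdown, by 1.39 (SE 0.34). Sugar starvation genes were lower (2 of 4 fell, 3 when adjusted over the list alone, median -0.96, adjusted p = 0.00231; adjusted p = 0.199 with an estimated correlation). AT1G73120 fell by 4.37 (SE 0.44) and EXPA8 by 2.00 (SE 0.32). Glycolysis genes were higher (3 of 4 rose, 3 when adjusted over the list alone, median 0.54, adjusted p = 0.000472; adjusted p = 0.0703 with an estimated correlation). Low-oxygen genes had a median of 1.08, with 6 of 18 increases and 11 when adjusted over the list alone (adjusted p = 2.15e-10; adjusted p = 0.116 with an estimated correlation). For ribosomal protein genes the median was 0.25 (1 of 7 rose, 3 when adjusted over the list alone, adjusted p = 0.0115; adjusted p = 0.342 with an estimated correlation). There were 1171 called probe sets, 604 higher and 567 lower; the count was 720 without 10 kPa replicate 2, 746 without 97 kPa replicate 2 and 716 without 97 kPa replicate 3.

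At 48 h shoots had lower Rubisco activase transcripts, on arrays where plant control genes were read more from the 3′ end at 10 kPa. The GAPDH 3′ to 5′ signal ratio was 83.5 ± 55.2 at 10 kPa and 16.1 ± 8.18 at 97 kPa, and the actin 3′ to middle ratio 9.86 ± 2.09 and 3.74 ± 0.105 (SD, n = 3). RCA, Rubisco activase, fell by 1.77 (SE 0.18, adjusted p = 1.35e-08), EXPA8 by 2.56 (SE 0.32) and AT5G59080 by 3.73 (SE 0.43). BGLU28, a beta-glucosidase, rose from 210.3 ± 37.9 to 3703 ± 987.3 (log2 change 4.06, SE 0.28), AT3G02480 by 7.43 (SE 1.16; 9.12 with no and 5.40 with the higher pseudocount) and APL3 by 1.87 (SE 0.41). AKINBETA1 fell by 2.77 (SE 0.31), EIN3, a transcription factor of ethylene signalling, by 0.77 (SE 0.13), and CSLA01, of the cellulose synthase-like family, rose by 4.11 (SE 0.66). With the ratio of each array as a covariate, the calls of AKINBETA1 (0.0503; -2.02, SE 0.54), EIN3 (0.79; -0.16, SE 0.21) and CSLA01 (0.42; 2.05, SE 1.14) ended, while RCA, EXPA8, BGLU28, AT3G02480, AT5G59080 and APL3 kept theirs. Sugar starvation genes were lower (3 of 4 fell, 3 when adjusted over the list alone, median -1.24, adjusted p = 0.0114; adjusted p = 0.285 with an estimated correlation), except with the covariate (0.218, median -0.62) and without 97 kPa replicate 3 (0.0695). Flavonoid genes were higher (3 of 4 rose, 3 when adjusted over the list alone, median 1.09, adjusted p = 0.0458; adjusted p = 0.285 with an estimated correlation). That call ended without 10 kPa replicate 2 (0.0721), 10 kPa replicate 3 (0.073), 97 kPa replicate 1 (0.0891) or 97 kPa replicate 3 (0.0519), and with the stricter filter (0.115) or no pseudocount (0.054). With the covariate it ended as well (0.057), although the median was larger, 1.32, as the median SE of the genes went from 0.40 to 0.74. Low-oxygen genes went both ways: 7 of 18 rose and 2 fell, 7 and 3 when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0991; adjusted p = 0.608 with an estimated correlation). This rested on 1 control array: without 97 kPa replicate 3 the median was 0.68 and the set was called higher (adjusted p = 8.9e-05; adjusted p = 0.136 with an estimated correlation). The 3750 called probe sets, 1637 higher and 2113 lower, became 215 with the covariate, 190 of them shared.

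At 72 h the low-oxygen genes of shoots no longer rose together, while all 4 flavonoid genes did. AT3G29970 was 3.55 higher (SE 0.37), but AT4G10270 fell by 2.67 (SE 0.33); 4 of 18 low-oxygen genes rose and 6 fell, 4 and 8 when adjusted over the list alone, with a median of -0.69 (adjusted p = 0.218; adjusted p = 0.783 with an estimated correlation), which was 0.08 without 10 kPa replicate 1. DFR rose by 2.24 (SE 0.35, adjusted p = 2.22e-05), and all 4 flavonoid genes rose, 4 when adjusted over the list alone, with a median of 1.77 (adjusted p = 0.00164; adjusted p = 0.116 with an estimated correlation). CSLA01 rose by 5.02 (SE 0.66), BGLU28 by 4.09 (SE 0.28) and COR15A by 2.25 (SE 0.41). RCA fell by 1.41 (SE 0.18), BCAT4 by 1.94 (SE 0.22), EIN3 by 1.04 (SE 0.13), UPB1, a transcription factor, by 3.68 (SE 0.58) and PDF1.2, a defensin gene, by 2.38 (SE 0.43, adjusted p = 0.000148). EXPA8 fell by 2.23 (SE 0.32), as at every time in shoots, and EXPA15 by 0.87 (SE 0.25, adjusted p = 0.0125), a call that ended without 10 kPa replicate 3 (0.0759). AKINBETA1 fell by 1.99 (SE 0.31) and JMT, a jasmonate methyltransferase, rose by 3.29 (SE 0.67), but these calls ended with the ratio covariate (0.052 at -1.45, SE 0.44, and 0.17 at 2.44, SE 0.99). The GAPDH ratio was 46.5 ± 8.94 at 10 kPa and 13.3 ± 1.91 at 97 kPa, and the actin ratio 8.13 ± 0.582 and 4.03 ± 0.449 (SD, n = 3). Of 3130 called probe sets, 1473 were higher and 1657 lower; 683 were called with the covariate, 595 of them shared.

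**Figure D3:**
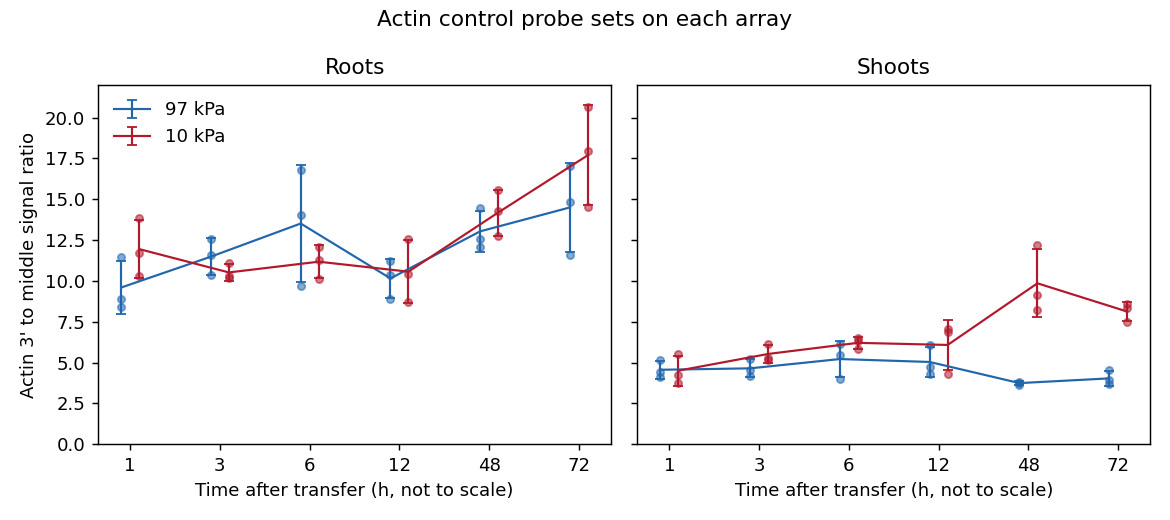
Ratio of the actin 3′ probe set signal to that of the middle probe set on each array against time in hours, in roots and shoots, at 97 kPa (blue) and 10 kPa (red). At 48 h the mean in shoots was 9.86 at 10 kPa against 3.74 at 97 kPa.

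Comparing the pressure effect late (mean of 48 and 72 h) with that early (mean of 1 and 3 h) asked whether the response changed with time. In roots, low-oxygen genes had a smaller pressure effect late: 13 of 18 fell in this contrast, 14 when adjusted over the list alone, with a median of -1.65 (adjusted p = 7.47e-23, and adjusted p = 0.0219 with an estimated correlation). AT4G30380 had a decrease of its effect of -3.64 (SE 0.75, adjusted p = 0.00214; -2.67 with the higher pseudocount). ICL had the largest gain, 3.92 (SE 0.88, adjusted p = 0.00489), which was not called without replicate 2 (0.127). Photosynthesis genes gained (2 of 9 rose, 4 when adjusted over the list alone, median 0.73, adjusted p = 0.00729; adjusted p = 0.47 with an estimated correlation). Of the 863 called probe sets, 365 were higher and 498 lower; the count was 455 without replicate 1, 274 without replicate 2 and 558 without replicate 3, and 1 of the 10 named genes kept its call in every alternative.

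Shoots had the same contrast in low-oxygen genes: 14 of 18 fell, 15 when adjusted over the list alone, with a median of -2.11 (adjusted p = 4.76e-14; adjusted p = 0.0668 with an estimated correlation). AT1G33055 had a change of effect of -3.93 (SE 0.49), AT4G10270 of -3.41 (SE 0.33) and AT3G10040 of -3.41 (SE 0.50). BGLU28 gained 4.78 (SE 0.28, adjusted p = 5.61e-14) and AT1G70270 3.15 (SE 0.35). CSLA01 gained 4.90 (SE 0.66), a call that ended with the ratio covariate (0.0769 at 3.25, SE 0.99). All 3 cell division genes had a lower effect late, 3 when adjusted over the list alone, with a median of -0.80 (adjusted p = 0.0315; adjusted p = 0.285 with an estimated correlation). Their call ended without replicate 1 (0.09) or replicate 3 (0.117) and with the covariate (0.264, median -0.40), over a range of 0.0059 to 0.264. The contrast called 2870 probe sets, 1220 higher and 1650 lower, against 1837 without replicate 2, 1648 without replicate 3 and 362 with the covariate.

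The controls themselves changed between the early and late times, and in shoots low-oxygen genes were part of that change. In control shoots 16 of the 18 low-oxygen genes were higher late, 18 when adjusted over the list alone, with a median of 1.75 (adjusted p = 2.16e-17; adjusted p = 0.0513 with an estimated correlation). Their median log2 signal per array went from 6.82 ± 0.59 at 1 h to 9.10 ± 0.12 at 72 h in control shoots, and from 9.44 ± 0.16 to 8.96 ± 0.19 in shoots at 10 kPa (SD, n = 3). Within 10 kPa shoots, late against early, 1 of 18 rose and 4 fell, with a median of -0.13 (p = 0.272, and p = 0.653 with an estimated correlation). All 4 dehydration genes were higher late in control shoots, 4 when adjusted over the list alone, with a median of 1.35 (adjusted p = 0.000714; adjusted p = 0.0639 with an estimated correlation). Photosynthesis genes were lower there (5 of 9 fell, 5 when adjusted over the list alone, median -0.41, adjusted p = 0.000472; adjusted p = 0.285 with an estimated correlation), except without replicate 3 (0.0644; range 3.42e-05 to 0.0644). In control roots 9 of 18 low-oxygen genes were higher late, 9 when adjusted over the list alone, with a median of 0.66 (adjusted p = 6.6e-07; adjusted p = 0.319 with an estimated correlation). Within 10 kPa roots, late against early, 1 of 18 rose and 10 fell, with a median of -0.78 (p = 2.45e-05, and p = 0.145 with an estimated correlation). Photosynthesis genes were higher in control roots (5 of 9 rose, 7 when adjusted over the list alone, median 0.90, adjusted p = 0.000683; adjusted p = 0.371 with an estimated correlation). Ribosomal protein genes were lower in control roots (1 of 7 rose and 6 fell, 1 and 6 when adjusted over the list alone, median -0.65, adjusted p = 4.92e-06; adjusted p = 0.147 with an estimated correlation). The controls of 6 and 12 h shared the number run of the late ones once the 4 arrays numbered apart were left out. Against them the late control shoots had a median of 1.53 in low-oxygen genes (p = 5.57e-20, and p = 0.00121 with an estimated correlation) and 0.98 in dehydration genes (p = 0.000532, and p = 0.0045 with an estimated correlation). Photosynthesis genes were at -0.11 (p = 0.191, and p = 0.498 with an estimated correlation), so their fall in control shoots could not be told apart from the number run. In control roots the medians were 0.57 in low-oxygen genes (p = 1.79e-05, and p = 0.145 with an estimated correlation), 1.01 in photosynthesis genes (p = 3.75e-06, and p = 0.0565 with an estimated correlation) and -0.62 in ribosomal protein genes (p = 6.25e-08, and p = 0.00912 with an estimated correlation). The comparison with 6 and 12 h, added after the results were seen, called 3131 probe sets in roots and 1442 in shoots. In control roots the GAPDH 3′ to 5′ ratio also differed: 81.0 to 179.2 at 1 and 3 h, 99.3 to 178.7 at 6 and 12 h and 190.6 to 1312 at 48 and 72 h. Ubiquitin ratios overlapped, with 4.17 to 7.81 at 1 and 3 h and 4.77 to 6.72 at 48 and 72 h. The 3 sets of control roots kept their late minus early calls with the ratio covariate. RNA quality as a source of part of these root changes stays open. The late minus early contrast called 4014 probe sets in roots, 1912 higher and 2102 lower, with 2338 without replicate 2 and 2390 without replicate 3, and 3548 in shoots, 1794 higher and 1754 lower, with 2351 without replicate 1.

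The difference between the tissues was tested as the root effect minus the shoot effect of pressure, averaged over the 6 times. Low-oxygen genes responded more in roots: 17 of 18 had a higher effect there, 17 when adjusted over the list alone, with a median of 2.23 and a range of 0.32 to 3.29 (adjusted p = 9.17e-28, and adjusted p = 0.00722 with an estimated correlation). AT5G26200 had a difference of 3.49 (SE 0.31, adjusted p = 1.66e-13), AT4G10270 of 3.29 (SE 0.25), AT4G30380 of 3.29 (SE 0.37; 2.06 with the higher pseudocount) and AT5G10040 of 3.09 (SE 0.32). AT1G73120, which fell in shoots at every time, had a difference of 3.53 (SE 0.33). In the other direction, JMT had a difference of -2.88 (SE 0.42), TBL26 of -2.67 (SE 0.36) and SHN3, a transcription factor of cuticle formation, of -2.35 (SE 0.44, adjusted p = 3.25e-05). JMT did not pass the filter in roots, so its difference does not measure a root response. AT3G02480, at -2.70 (SE 0.58), and CSLA01, at -2.28 (SE 0.46), were not called without the 48 and 72 h arrays (0.0537 and 0.294). Photosynthesis genes were more raised or less lowered in roots (5 of 9 higher, 5 when adjusted over the list alone, median 0.64, adjusted p = 0.00159; adjusted p = 0.362 with an estimated correlation), as were auxin genes (2 of 6 higher, 2 when adjusted over the list alone, median 0.62, adjusted p = 0.013; adjusted p = 0.0664 with an estimated correlation). Only 3 of the 6 auxin genes passed the filter in shoots. Each of the 7 ribosomal protein genes had a lower effect in roots, 7 when adjusted over the list alone, with a median of -0.31 (adjusted p = 0.000631; adjusted p = 0.216 with an estimated correlation). The contrast called 4629 of 17901 probe sets, 1991 with a higher and 2638 with a lower effect in roots. Time by time, it called 303 at 1 h, 329 at 3 h, 1130 at 6 h, 929 at 12 h, 1663 at 48 h and 1188 at 72 h.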

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

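Of the tests in this part, the covariate fit, the comparisons of marker genes, control signal ratios and number runs, and the spike comparison were chosen only after the results were seen. The predictions for RNA degradation and for all transcripts of shoots in roots were written before their values were known. The bound used for the root tissue test was rewritten after its value was seen, because an earlier bound could not be decided with markers so dim.

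Low-oxygen genes had a pressure effect that differed between early and late times, by a median log2 of -1.65 in roots (adjusted p = 0.0219 with an estimated correlation) and -2.11 in shoots, where the call did not hold (adjusted p = 0.0668 with an estimated correlation). In shoots the change lay mostly in the controls, where the 18 genes were 1.75 higher late than early (adjusted p = 0.0513 with an estimated correlation). RNA from roots in the late control shoots is argued against as the whole source: the share of root signal that the root hair gene EXPA7 would allow was 0.447% (SE 11.4), and that of EXPA18 was -5.68% (SE 5.71), where the 18 genes would need a median share of 66.2% and 6 of them over 100%. The lowest share needed by a gene was 5.43%, which lies within the error of EXPA7, so a part in some genes stays open. The median share of 66.2% would also put transcripts made only in shoots at -1.57 on the log2 scale, and photosynthesis genes stood at a median of -0.41, the lowest at -0.73. A difference between runs of array numbers is argued against too, since control shoots at 48 and 72 h were 1.53 higher than those at 6 and 12 h of the same run, against 1.71 over the early times. The GAPDH 3′ to 5′ ratio differed little between these controls, with a late to early ratio of 1.03 (SE 0.168). Other measures of these arrays did differ. The scaled signal of the cre spike was 39150 to 54490 at 1 and 3 h and 73580 to 112100 at 48 and 72 h. Correlations between replicates were 0.967 to 0.974 early and 0.906 to 0.950 late. Such differences between arrays, time in the chamber and the age of the plants remain open and untested.

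The 3′ to 5′ ratios of plant control genes were higher at 10 kPa than at 97 kPa in late shoots, in control probe sets that the comparisons do not use. At 48 h the means were 83.5 and 5.84 for the GAPDH probe sets, 9.86 for actin and 6.02 for ubiquitin; at 72 h they were 46.5 and 4.202 for GAPDH and 8.13 for actin. These 7 were found among 48 comparisons by asking for every 10 kPa array above every 97 kPa array and a mean over 1.5 times higher, and chance alone separates 5% of such comparisons upward. The mirrored search, made after these were seen, found 2 lower ratios at 10 kPa, both of the first GAPDH probe set in roots: 76.0 against 164.0 at 3 h and 155.0 against 272.1 at 48 h. The same shoots had more called probe sets than at earlier times in the fit of all times. With only the 6 arrays of each comparison, the count at 48 h was below that at 3 h. Uneven labelling is argued against: spiked bacterial transcripts, which join the RNA after harvest, differed by a median log2 of 0.10 (-0.207 to 0.236), where plant control genes differed by 1.22 (0.457 to 2.30).

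RNA degradation in the 10 kPa shoots cannot be told apart from the pressure response as a source of these calls. With the ratio as a covariate, probe sets called at 48 h kept 69.1% of their median size (0.79 before, 0.54 after), and those called at 72 h kept 81.9% (0.80 before, 0.66 after). The calls went from 3750 to 215 and from 3130 to 683, and the median SE went from 0.20 to 0.35 and from 0.20 to 0.29, so the calls ended through wider errors as well as smaller changes. The ratio is itself higher in the 10 kPa arrays of these groups, which is what keeps the question open. A biological difference between late and early shoots at 10 kPa stays open as well, untested.

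Photosynthesis genes had a higher pressure effect in roots than in shoots (median difference 0.64) and a higher effect late than early in roots (0.73). Neither call held with an estimated correlation, at adjusted p = 0.362 and adjusted p = 0.47. Green shoot tissue among the 10 kPa roots at 48 h cannot be told apart from a change in the roots. Over 300 probe sets at least 10 times higher in shoots, the 9 genes left out, the median share of shoot signal was 2.19% higher at 10 kPa (SE 1.23), where the 9 genes need a median of 3.84%. This difference met the bound written beforehand for shoot tissue as the source, but passed it by less than its SE. Of these probe sets 78 were called higher and none lower, and 1 of the 10 kPa arrays, at 4.21%, lay above the other 2, at 0.899% and 1.30%. Of the 9 genes RCA was at -0.49 (SE 0.35), PSBY at 1.65 (SE 0.32) and PSAE-1 at 1.87 (SE 0.35). RCA lay more than 2 SE below the 0.73 that the median share predicts. By a bound set after the results were seen, this counted against shoot tissue. The 2 bounds thus went opposite ways, and single genes do not decide it. What keeps the question open is the opposite results of the bounds, the spread between arrays and the way the 300 were chosen. Greening of the roots themselves was not tested.

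Further differences were found by the test of the difference between tissues or times. Cell division genes had a lower pressure effect late than early in shoots (-0.80; adjusted p = 0.285 with an estimated correlation), a call that ended without replicate 1 (0.09), without replicate 3 (0.117) and with the ratio covariate (0.264, median -0.40). Between roots and shoots, low-oxygen genes differed by a median of 2.23, ribosomal protein genes by -0.31 (adjusted p = 0.216 with an estimated correlation) and auxin genes by 0.62 (adjusted p = 0.0664 with an estimated correlation). Only 3 of the 6 auxin genes passed the filter in shoots. Single genes with a positive root minus shoot difference were AT1G73120 (3.53), which fell in shoots, AT5G26200 (3.49), AT4G10270 (3.29), AT4G30380 (3.29) and AT5G10040 (3.09). Those with a negative difference were JMT (-2.88), which did not pass the filter in roots, AT3G02480 (-2.70), TBL26 (-2.67), SHN3 (-2.35) and CSLA01 (-2.28). Of these, AT3G02480 (0.0537) and CSLA01 (0.294) were not called without the 48 and 72 h arrays. With the ratio covariate JMT lost its shoot calls at 3 h (0.0676), 48 h (0.316) and 72 h (0.17), and CSLA01 lost that at 48 h (0.42).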

How the results depend on the processing

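Leaving out the 48 and 72 h arrays and the ratio covariate were chosen after the data were seen; the other alternatives were planned. All 17 counts of called probe sets stayed within 1.5 times their value with quantile normalization, no or a higher pseudocount, no or a stricter filter, no variance trend and a replicate block, and so did those rerun with the tube as a random block or without the 4 arrays numbered apart. No named gene or list reversed. Of 376 gene results 196 kept their call in every alternative run, and of 51 list results 34 did. Genes lost calls mostly when 1 replicate was left out (357 of the reruns) or with the covariate (81 genes).

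A 2-fold minimum lowers every count by construction: in roots to 265, 488, 575, 776, 888 and 679 at 1, 3, 6, 12, 48 and 72 h, to 391 for late minus early and to 662 for the control contrast. In shoots it gave 260, 268, 654, 443, 1235, 1066, 860 and 505 in the same order, and for root minus shoot 732. The main fit takes 1 spread per probe set over all times of a tissue. With only the 6 arrays the spread comes from that time alone, and from fewer samples. Roots then gave 1219 at 1 h, 1745 at 3 h, 620 at 48 h and 422 at 72 h, and shoots 1523 at 3 h and 1224 at 48 h. Early counts thus rose and late counts fell in those comparisons, so the order of the times depends on that choice. Without the 48 and 72 h arrays, roots gave 1028 at 1 h, 1527 at 3 h and 2350 at 6 h, and shoots 1114 at 1 h; the cause was not tested. With the ratio covariate, shoots gave 215 at 48 h, 683 at 72 h and 362 for late minus early, with 190, 595 and 307 shared, partly through wider errors.

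Leaving out 1 replicate, which also removes samples, gave these ranges in roots: 331 to 471 at 1 h, 689 to 730 at 3 h, 1056 to 1267 at 6 h, 1262 to 2005 at 12 h, 1412 to 1859 at 48 h, 1055 to 1276 at 72 h, 274 to 558 for late minus early and 2338 to 3428 for the control contrast. In shoots they were 264 to 663, 307 to 714, 1222 to 1475, 716 to 939, 2898 to 3742, 2287 to 2698, 1648 to 2056 and 2351 to 2574, and for root minus shoot 3133 to 3328.

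The replicate numbers were not taken as pairs. With a replicate block the counts in roots were 534, 916, 1435, 1888, 1818 and 1263 over the 6 times, 782 for late minus early and 3818 for the control contrast, in shoots 636, 850, 1772, 1139, 3674, 3105, 2814 and 3483, and for root minus shoot 4541. At no time did arrays of the same number correlate above 0.1 in every pair after group means were removed, and of the 29 tubes with both tissues 1 did, with a median r of 0.017 across genes. Signal over background limits genes near the floor of the scale: their changes depend on the pseudocount, and the absence of a call there does not show that nothing changed.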

Other observations

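The tests of organelle genes below were chosen only after the annotation was seen, and they were not rerun under the alternatives; the splits of the samples were planned. RNA was labelled with a 3′ IVT kit, and whether it reads organelle transcripts as it does nuclear ones was not tested. Rises and falls of organelle genes are thus those of array signal, not shown to be those of transcript level. Genes of the chloroplast's own ribosome and RNA polymerase rose in shoots at 72 h: 9 of 14 rose, with a median of 0.84 (adjusted p = 0.000125; adjusted p = 0.996 with an estimated correlation). These are arrays on which the plant control genes had higher 3′ to 5′ ratios at 10 kPa (GAPDH 46.5 against 13.3, actin 8.13 against 4.03). Among the genes, rps16 rose by 1.31 (SE 0.29), rps15 by 1.23 (SE 0.34), rps18 by 1.08 (SE 0.21) and rpoC1 by 1.03 (SE 0.26). At 48 h, where the ratios of the plant control genes were also higher at 10 kPa, 4 of the 14 rose, with a median of 0.32 and no shift of the set (adjusted p = 0.17).

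Chloroplast genes of the photosynthetic complexes were lower in shoots at 1 h, with 2 of 33 called and a median of -0.30 (adjusted p = 0.000521; adjusted p = 0.996 with an estimated correlation). At 48 h the set was not called (adjusted p = 0.192; adjusted p = 0.996 with an estimated correlation). Of its genes 5 rose and petL fell by 0.55 (SE 0.20), while psbN rose by 1.49 (SE 0.37), psaJ by 0.95 (SE 0.33) and psbA by 0.87 (SE 0.29). On these arrays the GAPDH 3′ to 5′ ratio was higher at 10 kPa by a log2 of 2.30. Genes of mitochondrial respiratory complexes had a median of 0.60 in shoots at 3 h (adjusted p = 0.0474; adjusted p = 0.996 with an estimated correlation), with none of 8 called. In roots at 6 h the chloroplast ribosome and polymerase genes (median -0.64, adjusted p = 0.0474) and the photosynthetic complexes (median -0.47, adjusted p = 0.0479) were lower, with no gene called, and neither held, at adjusted p = 0.996 with an estimated correlation for both.

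Every other split of the same 6 arrays was fitted for each pressure comparison. There are 10 splits, too few for a share under 0.05. Each other split mixes the pressures, which turns a pressure effect into spread and lowers its calls. The real split called 594, 1000, 1531, 2001, 1918 and 1360 probe sets in roots at 1, 3, 6, 12, 48 and 72 h, and the highest other split 0, 0, 1, 1, 112 and 63. In shoots the real split called 689, 853, 1848, 1171, 3750 and 3130, and the highest other 1, 0, 0, 0, 622 and 4.

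For the contrasts over several times 100 splits were drawn, the real one included. In each case 1 of 100, the real one, called as many. The splits exchanged arrays between pressures within each tissue and time, or between times in the controls. That share thus speaks only against no pressure effect at all, or no difference at all between the control times. It cannot decide whether the pressure effect was the same early and late, or in both tissues. Exchanging arrays turns the pressure effect itself into spread, which lowers the calls of the other splits. Late minus early called 863 in roots against a highest other of 690, and 2870 in shoots against 1650. The control contrast called 4014 in roots against 1977 and 3548 in shoots against 1740. Root minus shoot called 4629 against 2.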
